A study of Mus musculus with 17 samples.

How the data were processed

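The samples were 17 mice described in the series title as aged, with no age in the labels. They comprised 4 wild-type (WT) mice, 5 APP/PS1 mice, 5 NLRP3 knockout mice and 3 APP/PS1.NLRP3 knockout mice, called double-mutant here. APP/PS1 mice carry transgenes that cause amyloid deposition, and NLRP3 is the sensor protein of an inflammasome. Per the labels' protocols, brain tissue was dissociated enzymatically, myelin was removed magnetically, and live cells positive for CD11b, an integrin subunit of microglia and other myeloid cells, were sorted singly into 384-well plates. Each plate held the cells of 1 mouse. Libraries were made by SORT-seq, a plate version of CEL-Seq2 in which each transcript's 3' end receives a well barcode and a unique molecular identifier (UMI).

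The submitters' processing notes name BWA 0.7.15, Seurat and genome build mm10, with no role or order of steps. The gene annotation and the counting program are not given in the sources used here. The authors deposited 3 tables per plate. The first holds the count of UMIs per gene and well, the second the count of reads, and the third an expected count of transcripts, which is the UMI count raised by a correction that grows with the count. UMI counts as deposited were used for the main tests, and the deposited expected counts were rounded to whole numbers after summing for an alternative. A deposited table of wells gives a library name, whether the authors kept the well, a cluster number without a name and the estimated transcript count. Its library names matched 1 sample only for WT replicate 1 and double-mutant replicate 3, so its other 15 libraries were not used. Genes are identified in the deposited tables by symbol and chromosome. Positions were taken by symbol from the RefSeq genes of GRCm38.p6, the same build as mm10, and 99.3% of 19289 gene names received one. Spike-in RNAs were left out of library sizes and tests.

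Because the deposited table also lists wells that the authors did not keep, cells were kept by a rule fixed beforehand: at least 500 UMIs, at least 300 genes and at most 20% mitochondrial UMIs. This kept 5556 cells of 6528 wells, 274 to 366 per mouse, with a median of 3932.5 to 8860 UMIs per kept cell. Sorting placed single cells in wells and no doublet caller was run. The cells were grouped into 12 clusters (2000 variable genes, 30 principal components, 20 neighbours, Leiden resolution 1; scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2). Clusters were named from markers fixed beforehand. A cluster of 192 border macrophage-like cells and an unnamed cluster of 288 cells with few UMIs were set aside, which left 5076 microglia. The UMIs summed over microglia ranged from 1310149 to 3333672 per mouse.

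The files and labels were searched for batches. Flow cells, 4 in all, were read from the plates' names; APP/PS1 and double-mutant mice shared none. Levels of Kcnq1ot1, Pot1b and Cxcr2 separated the plates into 2 library batches that the labels do not name. Batch 2 held WT replicates 3 and 4, APP/PS1 replicates 3 and 5 and NLRP3 knockout replicates 3 and 5, and no double-mutant mouse. Of 10253 genes, 438 were higher and 876 lower in batch 2, and these 1314 genes were kept out of clustering. Within each group, replicates differed by more than sampling noise, with a chi-square per degree of freedom of 2.85 to 24.16, so no plate was counted as a repeat of another.

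UMI counts were summed over the microglia of each mouse and tested with edgeR 4.0.16 in R 4.3.3. The fit was a robust quasi-likelihood model with group and sex, TMM scaling and the filterByExpr filter, over all 17 mice, which share 1 estimate of the spread. It tested 10121 genes at a common biological coefficient of variation of 0.198, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were APP/PS1 with WT, NLRP3 knockout with WT, double-mutant with APP/PS1, double-mutant with NLRP3 knockout, the interaction of both changes, and female with male mice. Gene lists for microglial states, immune signalling, metabolism, organelles, dissociation and other cell types were written beforehand; 745 of their 761 genes were matched, and the 23 lists with at least 3 tested members were compared with the other genes by camera in limma 3.58.1 at a preset correlation of 0.01. Camera with an estimated correlation and fry, which asks whether a list moves on balance in 1 direction, were alternatives. Levels of single genes are CPM over TMM-scaled UMI totals, as mean ± SD over mice. Summed markers of other cell types are CPM over UMI totals without TMM scaling. TMM factors were 0.8718 to 0.9188 in double-mutant and 1.04 to 1.084 in NLRP3 knockout mice. Without them the marker levels of double-mutant mice lie lower against those of NLRP3 knockout mice than with TMM scaling. Exact two-sided permutation tests compared shares of cells, UMIs per cell, quality measures and markers of other cell types (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, Python 3.11.15). For the shares of named clusters alone, 100000 permutations of residuals tested the interaction. The plots were drawn with matplotlib 3.10.9.

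The text names Nlrp3 and App; up to 10 higher and 10 lower genes per pairwise comparison with the largest fold change among called genes above the median expression that kept their sign with each mouse left out; up to 4 members with the smallest p of each list described; and 11 genes fixed beforehand, from Slc1a3 to Tmem119. Other genes are said to be chosen after their values were seen. Results of some genes are not reported here, and those genes were also left out of the search for outlying mice and of the tests of positions. A fold against a group with 0 counts was computed against a floor of 3 counts over the group and is a lower bound. With 1 to 3 counts, the ratio is given with a 95% interval for counting error.

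Simulated counts with known changes were used to check the tests. For APP/PS1 against WT, 16.4%, 58.2% and 86.4% of genes changed 1.5-, 2- and 4-fold were recovered; for the interaction, 1.5%, 19.4% and 72.7% were. Alternatives fixed before the data were examined were DESeq2 1.42.0, other scaling, filters, count types, covariates, cells and mice, and a replicate block. Terms for library batch, analyses within a batch, scaling by library size alone, wells with at least 1000 deposited transcripts and fry were added after the data were seen.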

Results

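Single-cell transcriptomes of CD11b-positive brain cells were collected from 4 WT, 5 APP/PS1, 5 NLRP3 knockout and 3 double-mutant mice, 1 plate of 384 wells per mouse. Female mice were WT replicate 1, APP/PS1 replicates 4 and 5, NLRP3 knockout replicates 4 and 5 and double-mutant replicate 3. Without spike-ins, the plates held 1506766 to 3500132 UMIs. Microglia made up 5076 of the 5556 kept cells. The clusters that held most of them differed between mice with and without the transgenes. Clusters 0 to 2 held 95.3% of WT and 96.3% of NLRP3 knockout microglia (clusters 0 and 1 87.6% in WT, clusters 0 and 2 80.8% in NLRP3 knockout), and clusters 3 to 6 held 58.5% of APP/PS1 and 78.0% of double-mutant microglia. In APP/PS1 replicate 5 clusters 3 to 6 held 12.5%. Cluster 2 was led by Ccr6, Ppcs, Tgm2 and Slc1a3. It held 19.7 to 76.4% of microglia in single NLRP3 knockout mice and 5.94% in double-mutant mice. Ccr6 and Ppcs are among the genes called below for NLRP3 loss, so this cluster is not separate evidence of a changed state. Values were computed over all microglia of a mouse unless a cluster is named.

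The targeted gene was examined first. Nlrp3, the inflammasome sensor (chromosome 11, 59541569 to 59566955, mm10), stood at 58.2 ± 15.4 CPM in WT (n = 4) and 89.5 ± 18.9 CPM in APP/PS1 microglia (n = 5). It stood at 1.33 ± 0.381 CPM in NLRP3 knockout (n = 5) and 3.37 ± 1.64 CPM in double-mutant microglia (n = 3). Each of the 8 knockout mice lay below each of the other mice. The labels do not say which part of the gene was deleted, and the 3' tags do not show whether the remaining UMIs come from an intact transcript.

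**Figure D1:**
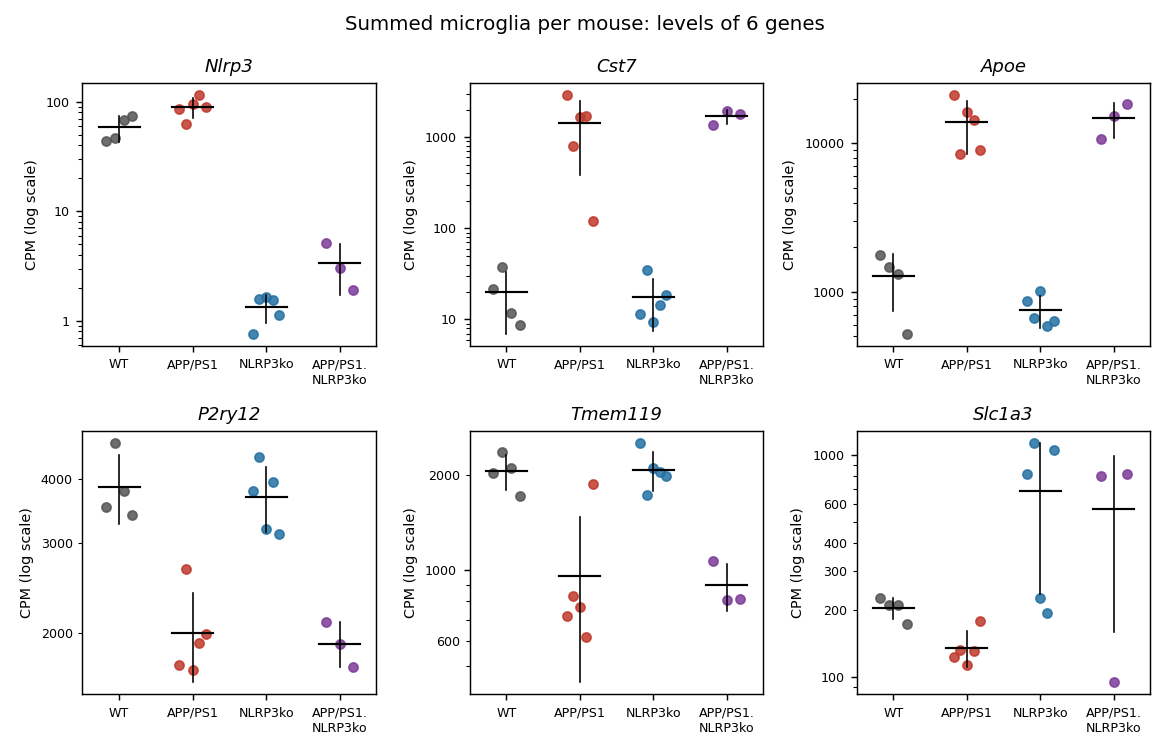
Each panel gives the level of a named gene in microglia, in CPM on a log scale, for every mouse by genotype; points are mice, horizontal lines are means and vertical lines are ± SD. Nlrp3 lay between 0.757 and 5.14 CPM in the knockout mice, while Cst7 averaged 1439 and 1694 CPM in the groups with the transgenes.

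To examine the transgene response with NLRP3 present, APP/PS1 microglia were compared with WT microglia. Cst7, an inhibitor of lysosomal cysteine proteases, rose from 20.03 ± 13.1 CPM (n = 4) to 1439 ± 1055 CPM (n = 5), a 73.3-fold difference (log2 fold change 6.20, SE 0.87, edgeR adjusted p = 0.000531). Apoe, a lipid-carrying protein, rose from 1268 ± 531 to 13890 ± 5333 CPM (log2 fold change 3.45, SE 0.38, adjusted p = 5.48e-05). Trem2, a lipid-sensing receptor, rose 2.06-fold (adjusted p = 0.000973). P2ry12, an ADP receptor of homeostatic microglia, fell from 3858 ± 590 to 2002 ± 395 CPM (adjusted p = 0.000327). Tmem119, a surface marker of microglia, was 2.2-fold lower (adjusted p = 0.00513). Other large increases were those of Baiap2l2 (235-fold), Mamdc2 (196-fold), the growth factor Igf1 (82.4-fold), Pianp (47.4-fold), Spp1 or osteopontin (41.6-fold), the heparan sulfate-cleaving enzyme Hpse (39.3-fold) and the fatty acid carrier Fabp5 (33.0-fold). Gpnmb, a glycoprotein of phagocytic cells, was 126-fold higher (adjusted p = 0.0257), and the adjusted p rose to 0.0602 to 0.0843 without any of the WT mice or without APP/PS1 replicate 1. The signalling adaptors Bank1 and Dok3 were 3.37- and 3.12-fold lower, and the sialic acid-binding receptor Siglece 3.3-fold lower. Tspan18 was 2.84-fold lower, Mtss1 2.78-fold, the organic anion transporter Slco4a1 2.69-fold, the transcriptional repressor Hes1 2.59-fold and Ggt5 2.51-fold.

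In all, 761 genes were higher and 471 lower of 10121 tested, and 2365 had an unadjusted p under 0.05. Within library batches 1 and 2, 1114 and 478 genes were called. With scaling by library size alone, which shifted the median of all genes to -0.185, 572 were higher and 930 lower, so 38.1% of calls were increases where TMM gave 61.8%. The count was 815 without APP/PS1 replicate 1. Nlrp3 itself was 1.54-fold higher (adjusted p = 0.0395), and this call was lost without WT replicate 1 (adjusted p = 0.263), WT replicate 2 or APP/PS1 replicate 1, 3 or 4. Il1b, the interleukin-1β gene, stood at 300 ± 251 CPM against 58.0 ± 33.5 CPM (adjusted p = 0.156). The inflammasome adaptor Pycard and protease Casp1 (adjusted p = 0.939 and 0.742), App (0.122), the glutamate transporter Slc1a3 (0.620) and glutamate dehydrogenase Glud1 (0.995) did not pass the test.

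Among the gene lists, 38 of 38 disease-associated microglia genes rose (38 adjusted over the list alone; camera adjusted p = 5.75e-66, 0.0123 with an estimated correlation). They included the receptor kinase Axl (14.3-fold), the pattern receptor Clec7a (16.8-fold), Cd52 (3.91-fold) and ferritin heavy chain Fth1 (2.31-fold). Of 24 homeostatic genes, 12 fell and 1 rose (17 and 1 adjusted over the list alone; adjusted p = 2.63e-09, 0.0474 with an estimated correlation). The fructose transporter Slc2a5 was 1.73-fold, the transcription factor Maf 1.77-fold and Selplg 1.75-fold lower. Of 74 ribosomal protein genes, 64 rose (68 adjusted over the list alone; adjusted p = 3.57e-55, 0.0474 with an estimated correlation), and Rps21 and Rpsa were 2.07- and 2.28-fold higher. Ribosomal protein genes have many pseudogene copies, as class I histocompatibility genes have paralogs, so reads can be shared within these families. Of 16 antigen presentation genes, 10 rose (11 adjusted over the list alone; adjusted p = 3.04e-10, 0.0123 with an estimated correlation). The invariant chain Cd74 was 12.8-fold, H2-D1 2.8-fold and B2m 1.99-fold higher.

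Metabolic and degradative genes also rose as lists. Of 21 glycolysis genes, 13 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 2.93e-08, 0.0317 with an estimated correlation). Aldoa, Pkm and Pgk1 were 2.31-, 2.28- and 2.9-fold higher. Of 46 lysosomal genes, 23 rose (25 higher and 1 lower adjusted over the list alone; adjusted p = 4.89e-13, 0.0474 with an estimated correlation). The tetraspanin Cd63 was 2.73-fold and the protease Ctsb 2.89-fold higher. Of 35 lipid and cholesterol genes, 17 rose (18 higher and 1 lower adjusted over the list alone; adjusted p = 3.78e-14, 0.0123 with an estimated correlation). The fatty acid synthesis enzyme Acaca was 8.08-fold higher. A further 6 lists were called with the preset correlation and not with an estimated one. Of 30 interferon response genes, 12 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 5.95e-08, 0.175 with an estimated correlation), with Ifi27l2a 6.24-fold higher. Of 70 oxidative phosphorylation genes, 11 rose (21 adjusted over the list alone; adjusted p = 1.41e-07, 0.320 with an estimated correlation), with Uqcrh 1.81-fold higher. Of 15 mitochondrially encoded genes 1 rose (1 adjusted over the list alone; adjusted p = 0.00368, 0.340 with an estimated correlation). Of 27 NF-κB and cytokine genes, 7 rose (9 higher and 1 lower adjusted over the list alone; adjusted p = 0.00283, 0.320 with an estimated correlation). The lipopolysaccharide co-receptor Cd14 and Tlr2 were each 2.78-fold higher. Of 36 phagocytosis genes, 9 rose and 6 fell (11 and 7 adjusted over the list alone; adjusted p = 0.0137, 0.241 with an estimated correlation), with the integrin subunit Itgax 30.9-fold higher. Of 28 autophagy genes, 6 rose (6 adjusted over the list alone; adjusted p = 0.0241, 0.241 with an estimated correlation), with the cargo receptor Sqstm1 1.71-fold higher. The medians of the phagocytosis and autophagy lists, 0.14 and 0.10 on the log2 scale, were smaller than the shift from scaling by library size alone, under which they were -0.02 and -0.05, so these lists were higher relative to the other genes; the autophagy list then lost its call (adjusted p = 0.0784).

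The inflammasome and interleukin-1 list was not called (camera adjusted p = 0.713, directed down, with a median log2 fold change of -0.01 and a mean of 0.21). The interleukin-1 receptor Il1r1 rose 6.0-fold, and Casp8, Txnip and Il18 fell. The call of Txnip was lost without WT replicate 3 (adjusted p = 0.0601), and Il18 kept its call in 4 of 17 fits with a mouse left out (adjusted p up to 0.128 without APP/PS1 replicate 1). Of 28 glutamine and glutamate genes, 4 rose and 1 fell (4 and 1 adjusted over the list alone; list adjusted p = 0.341). Among them the transaminase Got1 was 3.27-fold, the glutamine transporter Slc1a5 5.56-fold and the serine synthesis enzyme Psat1 5.14-fold higher, and Phgdh 1.61-fold lower. Lists for the tricarboxylic acid cycle (adjusted p = 0.677), α-ketoglutarate dioxygenases (0.677), complement (0.314), proliferation (0.998) and immediate early genes (0.677) were not called, nor were the tested marker lists of border macrophages (0.677), monocytes (0.459) and oligodendrocytes (0.691). Markers of T and NK cells stood at 14.6 ± 7.11 CPM (n = 5) against 28.7 ± 5.02 CPM (n = 4; exact permutation p = 0.0159, the smallest possible, adjusted 0.381), and dendritic cell markers at 10.9 ± 2.11 against 15.8 ± 3.12 CPM (exact permutation p = 0.0476, adjusted 0.381). Markers of astrocytes (34.6 against 23.2 CPM), B and plasma cells (15.6 against 22.6), endothelial cells (39.6 against 27.9), erythrocytes (0.143 against 0), neurons (22.8 against 26.6), neutrophils (453 against 494) and pericytes (1.75 against 2.01) had exact permutation p of 0.111 to 1.00. The neutrophil sum includes Cxcr2, which separated the library batches. Over all mice it was 523 to 578 CPM in batch 2 and 346 to 472 CPM in batch 1, so it follows the batch.

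To examine the same response without NLRP3, double-mutant microglia were compared with NLRP3 knockout microglia. Cst7 rose from 17.7 ± 10.2 CPM (n = 5) to 1694 ± 312 CPM (n = 3), 96.2-fold (log2 fold change 6.59, SE 0.82, edgeR adjusted p = 0.000162). Apoe rose 19.8-fold from 751 ± 179 to 14840 ± 3963 CPM, Trem2 2.87-fold from 934 ± 99.8 to 2685 ± 122 CPM, and P2ry12 was 1.95-fold lower (adjusted p = 5.11e-06, 2.69e-05 and 0.000484). Baiap2l2 was 165-fold, Igf1 75.2-fold, Hpse 72.4-fold, Fabp5 63.8-fold, Pianp 34.2-fold, the prolyl hydroxylase Egln3 31.9-fold and Spp1 31.6-fold higher. Gpnmb had 0 UMIs in NLRP3 knockout and 752 in double-mutant microglia and was at least 407-fold higher (adjusted p = 0.0182; 0.0676 without double-mutant replicate 3). Serpinf1 was 5.09-fold, Bank1 4.24-fold, Tspan18 4.01-fold, Slco4a1 3.96-fold, Upk1b 3.91-fold, the interferon-inducible GTPase Gbp7 3.76-fold and the C-type lectin Clec4a2 3.47-fold lower. Tmem119 was 2.29-fold lower (adjusted p = 0.00614; 0.0617 without double-mutant replicate 3).

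In this comparison 938 genes were higher and 644 lower, and 2756 had an unadjusted p under 0.05. Scaling by library size alone shifted the median to -0.291 and gave 649 higher and 1797 lower, so 26.5% of calls were increases where TMM gave 59.3%. The count was 835 without double-mutant replicate 3, and within library batch 1 it was 1654; batch 2 held no double-mutant mouse. App was 1.43-fold higher (adjusted p = 0.0292), a call lost without any of 6 mice, with the highest adjusted p, 0.134, without double-mutant replicate 3; the others were double-mutant replicate 1 and NLRP3 knockout replicates 1, 3, 4 and 5. Il1b stood at 599 ± 273 CPM against 80.5 ± 55.1 CPM (adjusted p = 0.0572). Nlrp3 (adjusted p = 0.0718), Slc1a3 (0.839), Glud1 (0.991), Pycard (0.294) and Casp1 (0.821) did not pass the test.

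All 38 disease-associated genes rose (38 adjusted over the list alone; camera adjusted p = 1.47e-62, 0.0170 with an estimated correlation), with Cd63 4.46-fold and Clec7a 20.5-fold higher. Increases were called for 69 of 74 ribosomal protein genes (74 adjusted over the list alone; adjusted p = 1.03e-75, 0.0190 with an estimated correlation), 25 of 46 lysosomal genes (31 higher and 1 lower adjusted over the list alone; 4.07e-19, 0.0190), 15 of 21 glycolysis genes (15 higher and 2 lower; 8.66e-09, 0.0190), 18 of 35 lipid and cholesterol genes (20 higher and 2 lower; 1.98e-12, 0.0170) and 8 of 16 antigen presentation genes (10 higher; 2.73e-06, 0.0385). Examples were Rps21 (2.49-fold), Ctsb (3.41-fold), the lactate transporter Slc16a3 (2.59-fold), Soat1, which esterifies cholesterol (2.52-fold), and Nlrc5, an activator of class I genes (3.42-fold). Of 24 homeostatic genes, 12 fell and 1 rose (13 and 1 adjusted over the list alone; adjusted p = 3.26e-05, 0.180 with an estimated correlation). The transcription factor Sall1 was 1.64-fold lower. Of 70 oxidative phosphorylation genes, 26 rose (36 adjusted over the list alone; adjusted p = 1.08e-13, 0.145 with an estimated correlation), with Cox6a1 2.06-fold higher. Of 15 mitochondrially encoded genes 10 rose (12 adjusted over the list alone; adjusted p = 2.55e-07, 0.114 with an estimated correlation), with mtCo1 1.8-fold higher. The median share of mitochondrial UMIs per kept cell was 11.1 ± 1.04% in double-mutant mice (n = 3) and 7.72 ± 0.888% in NLRP3 knockout mice (n = 5; exact permutation p = 0.0357, the smallest possible, adjusted 0.381).

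Of 30 interferon response genes, 11 rose and 1 fell (12 and 1 adjusted over the list alone; camera adjusted p = 3.09e-06, 0.223 with an estimated correlation), with the antiviral tether Bst2 2.19-fold higher. Of 28 immediate early genes, the list written for dissociation, 6 fell (10 adjusted over the list alone; adjusted p = 0.000416, 0.351 with an estimated correlation). Fos was 2.08-fold and Socs3 2.01-fold lower, with adjusted p of 0.0905 and 0.114 without double-mutant replicate 3. Whether tissue dissociation or genotype moved these genes was not tested. NF-κB and cytokine genes (6 higher and 2 lower of 27; 7 and 3 adjusted over the list alone; adjusted p = 0.0479, 0.428 with an estimated correlation) and phagocytosis genes (10 higher and 5 lower of 36; 11 and 6 adjusted over the list alone; adjusted p = 0.0102, 0.223 with an estimated correlation) were called with the preset correlation. With relative log expression scaling the adjusted p of the NF-κB and cytokine genes was 0.0551. The median of the phagocytosis genes was 0.12 on the log2 scale and turned to -0.13 with scaling by library size alone, so this list was higher relative to the other genes. Lists for autophagy (adjusted p = 0.154), glutamine and glutamate (0.391), the tricarboxylic acid cycle (0.391), the inflammasome (0.362), complement (0.418), proliferation (0.388) and α-ketoglutarate dioxygenases (0.388) were not called by camera. Of these lists, fry called autophagy and the tricarboxylic acid cycle as higher (fry adjusted p = 0.01275 and 0.005826) and the inflammasome as lower (0.04439). T and NK cell markers stood at 6.93 ± 1.37 CPM in double-mutant and 23.2 ± 5.15 CPM in NLRP3 knockout mice, and dendritic cell markers at 8.13 ± 3.46 and 16.4 ± 5.16 CPM (exact permutation p = 0.0357 for each, the smallest possible, adjusted 0.381).

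**Figure D2:**
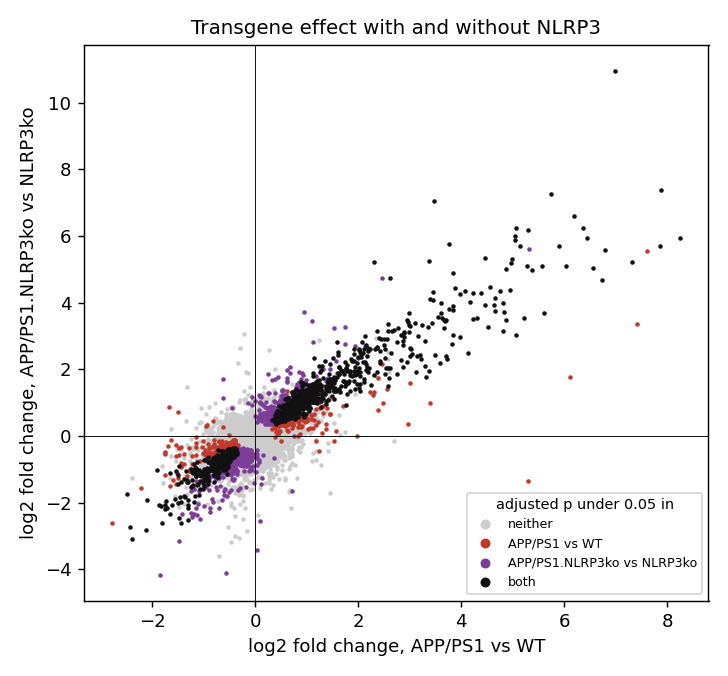
Each point is a tested gene, with its log2 fold change in APP/PS1 against WT on the horizontal axis and in double-mutant against NLRP3 knockout microglia on the vertical axis, coloured by whether the adjusted p was under 0.05 in neither, 1 or both. The correlation across genes was 0.819.

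The transgene effects with and without NLRP3, which share no library, were then set against each other over 10121 genes. Their log2 fold changes correlated with r = 0.819 and rho = 0.659, with a major-axis slope of 1.11; genes are not independent replicates. Of the genes called, 636 were higher in both comparisons, where independent lists would share 70.5, and 314 were lower in both, where 30 would be shared; 0 were called in opposite directions. Cst7, Apoe, Axl, Clec7a and Cd63 were among those higher in both, and P2ry12, Bank1, Tspan18 and Slco4a1 among those lower in both. Within library batch 1 the correlation was 0.742, and among cells of cluster 0, the largest, it was 0.0930. That cluster held 37.0% of WT, 39.9% of NLRP3 knockout, 22.6% of APP/PS1 and 4.99% of double-mutant microglia. The cluster was led by Egr1, Fosb and Dnajb1, and Fos and Socs3 of the list for dissociation were among its top genes. It was formed on these same expression values, so its cells were selected to be alike. Mice with the transgenes had 6 to 148 cells in it. Its correlation therefore does not test whether the transgene effects match.

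To examine loss of NLRP3 without the transgenes, NLRP3 knockout microglia were compared with WT microglia. Besides Nlrp3, which was 42.7-fold lower (log2 fold change -5.42, SE 0.31, edgeR adjusted p = 8.06e-11), 8 genes were called. Ccr6, a chemokine receptor (chromosome 17, 8236041 to 8258519), rose from 1.33 ± 0.445 to 104 ± 36.0 CPM, 72.7-fold (adjusted p = 3.88e-09). Ppcs, an enzyme of coenzyme A synthesis (chromosome 4, 119418527 to 119422440), rose 7.67-fold from 10.7 ± 4.04 to 84.2 ± 22.9 CPM (adjusted p = 1.47e-06). The mitochondrial malic enzyme Me2 rose 2.48-fold (adjusted p = 0.00333). Mib2, a ubiquitin ligase, fell from 99.6 ± 6.02 to 42.6 ± 9.80 CPM (2.33-fold, adjusted p = 0.00229). Mpc1, a subunit of the mitochondrial pyruvate carrier (chromosome 17, 8283787 to 8297667), fell from 131 ± 19.7 to 67.2 ± 10.9 CPM (1.9-fold, adjusted p = 0.00141). Named after its values were seen, the pseudogene Tmem181c-ps, which can share reads with its paralogs, was higher (adjusted p = 0.00498). Cd300lf, an inhibitory receptor, was 47.1-fold higher (adjusted p = 0.0197), a call lost without WT replicate 1, 2, 3 (adjusted p = 0.128) or 4 or NLRP3 knockout replicate 2.

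Thus 5 genes were higher and 4 lower; 405 had an unadjusted p under 0.05, DESeq2 called 26, library batches 1 and 2 gave 6 and 15, and the count was 14 without APP/PS1 replicate 5. With flow cell as a term, 4 of the 7 genes reported here other than Nlrp3 were still called. Among those that lost the call, the adjusted p of Cd300lf was 0.215 and that of Mib2 0.0750. Slc1a3 stood at 684 ± 447 CPM against 206 ± 22.6 CPM (adjusted p = 0.998), and App, Glud1, Il1b, Pycard, Casp1, Apoe, Trem2, Cst7, P2ry12 and Tmem119 had adjusted p of 0.998. With the preset correlation 3 lists were called, with 0 members called in any of them over all genes or adjusted over the list alone. Immediate early genes, the list written for dissociation, ranked higher (median log2 fold change 0.29 over 28 genes; camera adjusted p = 5.39e-06, 0.625 with an estimated correlation). Whether tissue dissociation or genotype moved them was not tested. The 15 mitochondrially encoded genes ranked lower (median -0.19; adjusted p = 0.000762, 0.625 with an estimated correlation) and 20 proliferation genes lower (median -0.53; adjusted p = 0.00498, 0.625 with an estimated correlation). The median share of mitochondrial UMIs was 7.72 ± 0.888% (n = 5) against 9.08 ± 0.550% (n = 4; exact permutation p = 0.0476, adjusted 0.381). The number of lists was 5 without WT replicate 1 or 3, APP/PS1 replicate 2, NLRP3 knockout replicate 1 or 4, or double-mutant replicate 3.

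**Figure D3:**
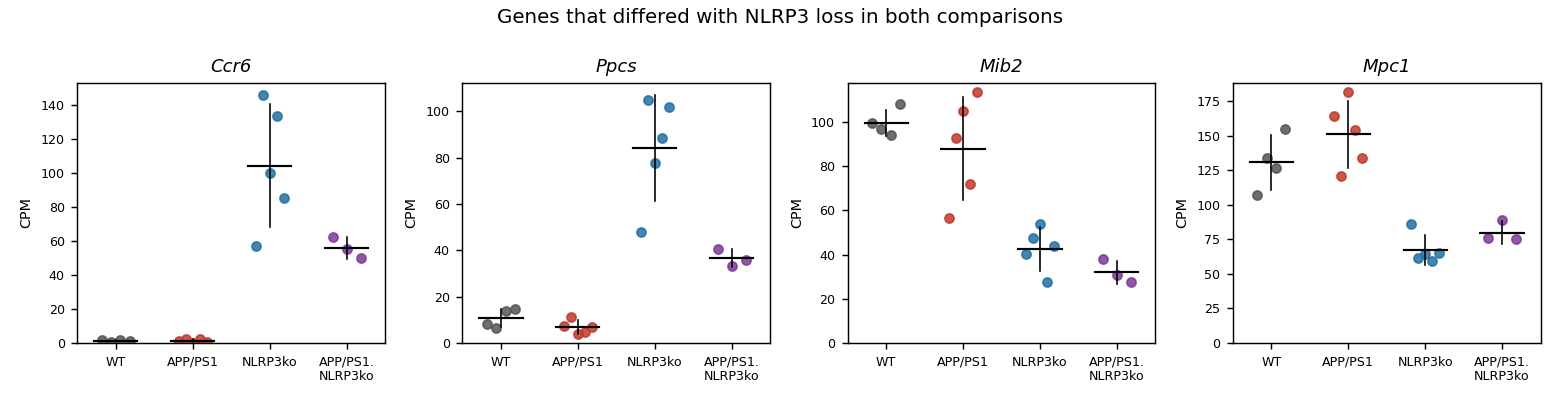
Levels of Ccr6, Ppcs, Mib2 and Mpc1 in microglia are given in CPM on a linear axis from 0, for every mouse by genotype; points are mice, horizontal lines are means and vertical lines are ± SD. Mib2 averaged 99.6 CPM in WT and 88.1 CPM in APP/PS1 mice, and 42.6 and 32.1 CPM in NLRP3 knockout and double-mutant mice.

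To examine loss of NLRP3 in mice with the transgenes, double-mutant microglia were compared with APP/PS1 microglia. Nlrp3 was 26.1-fold lower (log2 fold change -4.70, SE 0.31, edgeR adjusted p = 1.60e-09). Ccr6 rose 40.1-fold to 56.0 ± 6.26 CPM (adjusted p = 3.78e-08), Ppcs 5.41-fold to 36.55 ± 3.801 CPM (adjusted p = 0.000122), the lysosomal sulfatase Sgsh 5.69-fold from 11.7 ± 9.36 to 58.6 ± 1.54 CPM (adjusted p = 0.00273) and Me2 2.54-fold (adjusted p = 0.00250). Mib2 fell 2.74-fold to 32.1 ± 5.22 CPM (adjusted p = 0.00115) and Mpc1 1.91-fold to 80.0 ± 8.02 CPM (adjusted p = 0.00250; 0.0576 without double-mutant replicate 1). Ctla2b was 2.17-fold higher (adjusted p = 0.00529), a call lost without double-mutant replicate 1 (adjusted p = 0.126) or 2. The glycosyltransferase gene Gcnt1 was 2.73-fold higher (adjusted p = 0.0104), a call lost without double-mutant replicate 1 (adjusted p = 0.126) or 2 or APP/PS1 replicate 1 or 5. Named after its values were seen, Fam189a2 had 87 UMIs in APP/PS1 and 0 in double-mutant microglia, at least 18.5-fold lower.

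In all, 10 genes were higher and 8 lower, 621 had an unadjusted p under 0.05, and 6 were called with flow cell as a term, among them Nlrp3, Ccr6 and Ppcs. With that term Sgsh, Gcnt1, Ctla2b, Mib2, Mpc1 and Me2 kept their signs and lost their calls (adjusted p of 0.286, 0.865, 0.865, 0.538, 0.461 and 0.166). Within library batch 1, which held every double-mutant mouse, 18 genes were called. Cst7 (adjusted p = 0.956), Apoe (0.971), Trem2 (0.808), P2ry12 (0.947), Tmem119 (0.976), Il1b (0.871), Pycard (0.833), Casp1 (0.887), Glud1 (0.800) and App (0.808) did not pass the test, nor did Slc1a3, at 571 ± 412 against 136 ± 24.9 CPM (0.619). Between this comparison and that without the transgenes, 4 genes were higher in both and 4 lower in both, where 0.00494 and 0.00316 would be shared by independent lists (Fisher's exact p = 2.40e-12 and 1.60e-13). Those lower in both include Nlrp3, the targeted gene, whose fall was fixed by the design. The p for the lower genes counts it and so overstates their overlap. Both p also treat genes as independent, while Ccr6, Tmem181c-ps and Mpc1 of the shared genes lie near each other on chromosome 17.

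With the preset correlation 5 lists ranked higher in double-mutant than in APP/PS1 microglia. Of 46 lysosomal genes, 1 rose, Sgsh (1 adjusted over the list alone; camera adjusted p = 1.29e-08, 0.614 with an estimated correlation). Of the 74 ribosomal protein genes (adjusted p = 4.06e-22, 0.614 with an estimated correlation), 70 oxidative phosphorylation genes (1.45e-06, 0.753), 38 disease-associated genes (0.000854, 0.879) and 21 glycolysis genes (0.0484, 0.753), 0 were called over all genes or adjusted over the list alone. APP/PS1 replicate 5 had the lowest share of microglia with disease-associated markers of its genotype, 26.9%. Without it the disease-associated and glycolysis lists were not called (adjusted p = 0.752 and 0.148), and the homeostatic list was called as higher (0.0382). Without APP/PS1 replicate 2 the former 2 lists were also not called (0.0903 and 0.308), which left 3 lists, nor were they within library batch 1 (0.462 and 0.0696), where the interferon response list was called as lower (0.00154; 0.793 with all mice). With flow cell as a term 1 list was called.

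The interaction tested whether the effect of NLRP3 loss differed between mice with and without the transgenes. With edgeR 0 genes were called, with DESeq2 0, and 330 had an unadjusted p under 0.05; 0 were called within library batch 1. Without a filter on low counts 39 were called, 11 higher and 28 lower, and in male mice alone 1 was. The lysosomal tetraspanin Cd63 had the smallest p of the disease-associated list (log2 difference 0.71, SE 0.26, edgeR adjusted p = 1.00), and for Cst7, Apoe, Trem2, P2ry12, Tmem119 and Il1b the log2 differences were 0.39, 0.85, 0.48, -0.04, -0.06 and 0.58, also with adjusted p of 1.00. With the preset correlation 5 lists were called: ribosomal protein, oxidative phosphorylation, mitochondrially encoded and lysosomal genes ranked higher and immediate early genes lower, with adjusted p of 0.568 for each with an estimated correlation. The immediate early genes are the list written for dissociation. The number of lists was 8 without APP/PS1 replicate 3, 9 without APP/PS1 replicate 5 and 8 with scaling by library size alone.

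**Figure D4:**
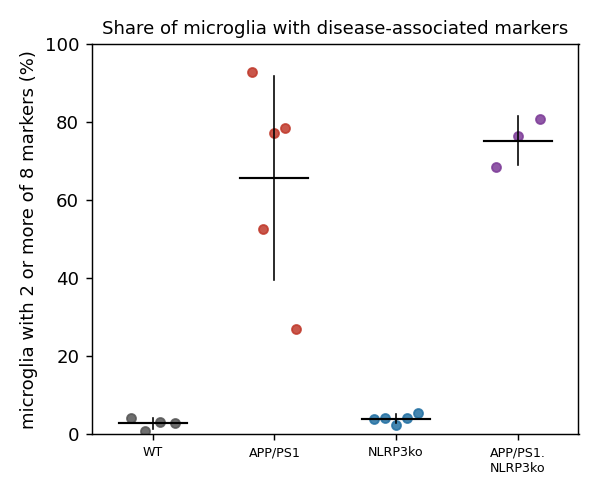
The percentage of microglia with UMIs of 2 or more of 8 disease-associated markers, after thinning each cell to 2000 UMIs, is given for every mouse by genotype; points are mice, horizontal lines are means and vertical lines are ± SD. Mice with the transgenes lay between 26.9 and 93.0%, and mice without them between 0.803 and 5.28%.

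To compare single cells, microglia were thinned to 2000 UMIs and counted where they held UMIs of 2 or more of Cst7, Lpl, Clec7a, Itgax, Spp1, Gpnmb, Csf1 and Axl, a bound set after the data were seen that marks a range and not a cell type. Such cells made up 2.69 ± 1.40% of WT microglia (n = 4) and 65.7 ± 26.1% of APP/PS1 microglia (n = 5; exact permutation p = 0.0159, the smallest possible, adjusted 0.0635). They made up 3.90 ± 1.12% in NLRP3 knockout (n = 5) and 75.3 ± 6.17% in double-mutant mice (n = 3; exact permutation p = 0.0357, the smallest possible, adjusted 0.0714). Neither NLRP3 knockout against WT (exact permutation p = 0.206) nor double-mutant against APP/PS1 (exact permutation p = 0.643) passed the test. With 4 or more markers the double-mutant minus APP/PS1 difference turned from 9.61 to -4.59 points, and the transgene differences went from 63.01 to 37.96 points with NLRP3 and from 71.4 to 33.3 points without it. In library batch 2 the values were 3.14 and 2.67% in WT and 77.3 and 26.9% in APP/PS1 mice. Unthinned shares were 9.25, 78.2, 9.96 and 91.9% in WT, APP/PS1, NLRP3 knockout and double-mutant mice, 25, 38, 27 and 12 shallower cells were left out, and 796 cells held 1 marker and 458 held 2.

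Border macrophage-like cells numbered 4.88 ± 3.36 per 100 microglia in NLRP3 knockout and 4.06 ± 2.47 in WT mice (exact permutation p = 0.603). They numbered 3.10 ± 2.13 in double-mutant and 2.95 ± 1.75 in APP/PS1 mice (exact permutation p = 0.929). Interferon microglia-like cells, led by Ifit3, Ifit2 and Ifit1, numbered 1.02 ± 0.273 in NLRP3 knockout and 1.73 ± 1.45 in WT mice (exact permutation p = 0.476), and 0.945 ± 1.01 in double-mutant and 2.22 ± 1.43 in APP/PS1 mice (p = 0.214). Cycling microglia-like cells, led by Top2a and Mki67, numbered 0.451 ± 0.429 in APP/PS1, 0.576 ± 0.797 in WT, 0.194 ± 0.289 in NLRP3 knockout and 0.498 ± 0.434 in double-mutant mice. Exact permutation p was 0.746 for APP/PS1 and 0.571 for NLRP3 knockout against WT, and 1.00 for double-mutant against APP/PS1. Median UMIs per kept cell were 7074 ± 528 in double-mutant (n = 3) and 5424 ± 1093 in NLRP3 knockout mice (n = 5; exact permutation p = 0.0714, the smallest possible being 0.0357; adjusted 0.286). In the other 3 comparisons the exact permutation p was 0.270 to 0.393.

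Female and male mice differed in 5 higher and 5 lower genes; 370 had an unadjusted p under 0.05, library batches 1 and 2 gave 6 and 14, and the count was 6 without WT replicate 1, APP/PS1 replicate 3, or NLRP3 knockout replicate 1 or 5. Xist, the X-inactivation RNA, was higher (log2 fold change 7.46, SE 0.26, edgeR adjusted p = 3.54e-11) and the Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were lower in female mice (log2 fold changes -8.86, -8.35, -8.57 and -10.14). The X-linked histone demethylase gene Kdm6a was higher (log2 fold change 0.79, adjusted p = 0.00470). Named after their values were seen, Tlr7, Ddx3x and Fam65b were higher and Pcp4 lower, with adjusted p of 0.0379, 0.0454, 0.0379 and 0.0261. They kept their calls in 5, 2, 3 and 9 of 17 fits with a mouse left out, with adjusted p up to 0.238, 0.250, 0.251 and 0.101. Nlrp3, App, Apoe, Cst7 and P2ry12 had adjusted p of 1.00.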

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

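In this part, the tests of a wrong label and of depth for APP/PS1 replicate 5 were chosen after the result was seen. Dixon's criterion was applied 552 times, each time to a gene or measure within a group of 4 or 5 mice. In 35 of these tests a mouse lay apart from the others of its group, where chance gives about 27.6. The tests share mice and are not independent, and APP/PS1 replicate 5 was flagged repeatedly.

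In APP/PS1 replicate 5, genes that were lower in APP/PS1 mice lay above the other 4 mice: Siglece stood at 73.33 CPM, Dok3 at 47.24, Grap at 73.33, Ggt5 at 30.32, Selplg at 2865.55, Tmem119 at 1872.05, P2rx7 at 172.75, Serpinf1 at 59.93, Upk1b at 214.35, Crybb1 at 277.11 and P2ry6 at 203.07 CPM. Slc1a3 stood at 178.39 CPM there, and border macrophage-like cells at 5.938 per 100 microglia. Rpsa was highest in APP/PS1 replicate 1 at 1003.96 CPM.

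Of WT mice, replicate 2 stood apart with Pianp at 15.27, Spp1 at 38.55 and Pycard at 172.38 CPM above the others, and Gsdmd at 122.2 CPM below them. Replicate 1 had Grap at 57.18, Phgdh at 64.61 and mt-Rnr1 at 6466.61 CPM below the others and Egln3 at 9.15 CPM above them. Replicate 4 had Hk3 at 150.81 CPM above the others and 3.883 interferon microglia-like cells per 100 microglia.

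Of NLRP3 knockout mice, replicate 1 had Mpc1 at 86.25 and Ctsz at 1191.64 CPM above the others and Rgs1 at 408.94 CPM below them. Replicate 2 had Maf at 791.74 and Pcna at 209.13 CPM, replicate 3 Naglu at 110.69 and Me2 at 49.87 CPM, replicate 4 Cd14 at 457.84 CPM and replicate 5 Acaca at 10.17 CPM, all above the others. Mamdc2 at 0.57 CPM in replicate 5 was 1 UMI, against 0 in the other 4 mice, which always meets the criterion and does not set that mouse apart. Rpl37a was lowest in replicate 4, at 345.97 CPM.

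The test of the interaction called 5 gene lists, with camera adjusted p of 2.657e-06 for oxidative phosphorylation, 1.499e-05 for mitochondrially encoded genes, 2.349e-05 for lysosomal genes, 7.752e-15 for ribosomal protein genes and 5.645e-07 for immediate early genes. Their adjusted p = 0.568 with an estimated correlation, and fry called 0 lists.

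The authors' deposited table of wells gives clusters without names, which the comparisons did not use, and its library names matched 1 sample for 2 of the plates. Cluster 0 held 64.05% of the 331 cells that the authors kept in double-mutant replicate 3 (exact 95% interval 58.62 to 69.22) and 0.59% of 337 in WT replicate 1 (0.07 to 2.13). Cluster 3 held 20.24% (16.05 to 24.98) and 7.12% (4.62 to 10.41). These intervals cover counting error only, and each genotype is 1 mouse.

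APP/PS1 replicate 5 had a weaker response than the other APP/PS1 mice, with a slope of 0.4162 on the transgene response, against 0.7432 to 1.313 in the others and 0.009787 to 0.1751 in mice without the transgenes. Fewer UMIs per cell are argued against, since after thinning to equal UMIs 26.91% of its microglia held 2 or more markers, against 52.65% in the next mouse. A transgene-free mouse under a wrong label would have a slope of at most 0.1751, while its Prnp level of 2.115 CPM, from 3 UMIs, lay within the transgene-free range of 0 to 2.287 CPM and below the 16.77 to 41.1 CPM of the other mice with the transgenes. These values point opposite ways, so a wrong label cannot be told apart from a weak response. Whether Prnp follows the response of the cell stays open, because the 41 marker-free cells of the other 4 APP/PS1 mice held 3 Prnp UMIs.

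Other splits of the mice into groups of the same sizes were fitted for each count. For APP/PS1 against WT, 2 of 100 splits called as many genes as the real one (1232; highest other 1614, a split that grouped APP/PS1 replicate 5 with the WT mice). For double-mutant against NLRP3 knockout 1 of 56 did (1582; highest other 2), and for the correlation of both transgene effects 1 of 100 did (0.819; highest other 0.7133). Chance is excluded at 0.05 for these 3 results. For NLRP3 knockout against WT 2 of 100 did (9; highest other 520), and for sex 2 of 100 did (10; highest other 395). In both, the highest split followed the library batches and called many more genes than the real one, which points to a structure of the samples; within batches 1 and 2, 6 and 15 genes were called for NLRP3 knockout and 6 and 14 for sex.

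Chance is not excluded for the next counts. For double-mutant against APP/PS1, 3 of 56 splits called as many genes (18; highest other 128, a split that grouped APP/PS1 replicates 2, 3 and 5 and so points to a structure of the samples). For the lists, 6 of 100 splits did for APP/PS1 against WT (13; highest other 15), 59 of 100 for NLRP3 knockout against WT (3; highest other 9), 44 of 56 for double-mutant against APP/PS1 (5; highest other 11), 7 of 56 for double-mutant against NLRP3 knockout (13; highest other 14) and 65 of 100 for the interaction (5; highest other 14). For the genes of the interaction the splits decide nothing, since with 0 called each of the 100 splits gave as many (highest other 6).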

How the results depend on the processing

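Terms for library batch, analyses within a batch, library size alone, fry, wells with at least 1000 transcripts and the marker share with its settings were chosen after the data were seen. Of the named genes' values under alternatives, 10920 kept direction and side of the threshold, 423 lost the call, 73 gained one, 307 uncalled values changed sign and 14 calls reversed. All kept cells stand in for the cells of the deposited table, which also lists wells the authors did not keep. The causes of the changes below were not tested. The largest cluster was formed on the same expression values, so results within it come from cells selected to be alike.

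For APP/PS1 against WT, the 1232 genes became 807 with a mean CPM of at least 50, 415 with read counts, 787 with only the groups compared, 11 in the largest microglia cluster, 324 with cells thinned to 500 UMIs and 478 in library batch 2. The 13 lists became 6 in the largest cluster and 7 with an estimated correlation. For NLRP3 knockout against WT, the 9 genes became 88 with no filter on low counts, 3 with a mean CPM of at least 50, 16 with only the groups compared, 3 with thinned cells, 21 with library batch as a term, 15 in batch 2 and 26 with DESeq2. The 3 lists became 5 with flow cell, 5 in batch 1, and 0 with an estimated correlation and with fry. For double-mutant against APP/PS1, the 18 genes became 164 with no filter, 3 with a mean CPM of at least 50, 3 with read counts, 6 with flow cell, 6 in the largest cluster and 1 with thinned cells. The 5 lists became 1 with flow cell, 1 in the largest cluster, 3 with library batch, and 0 with an estimated correlation and with fry. For double-mutant against NLRP3 knockout, the 1582 genes became 1006 with a mean CPM of at least 50, 534 with read counts, 8 in the largest cluster, 446 with thinned cells, 862 in male mice and 2446 with library size alone. The 13 lists became 7 in the largest cluster and 6 with an estimated correlation. For the interaction, the 0 genes (330 at an unadjusted p under 0.05 with edgeR, 0 called with DESeq2) became 39 with no filter and 1 in male mice. The 5 lists became 2 in the largest cluster, 8 in batch 1, 8 with library size alone, and 0 with an estimated correlation and with fry. For sex, the 10 genes became 38 with no filter, 6 each with a mean CPM of at least 50, read counts, flow cell, the largest cluster and batch 1, and 3 with thinned cells.

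Over 22 same-numbered pairs of mice the correlation of deviations ran from -0.26 to 0.378, with a median of 0.068. Over the 85 other pairs it ran from -0.346 to 0.343, with a median of -0.032. It was over 0.1 in 10 and 24 of these pairs, and 7 mice correlated best with their own number. All mice numbered 1 or 2 were in library batch 1 and all numbered 5 in batch 2. Among mice numbered 1, 2 or 5, a shared number thus always came with a shared batch. Same-numbered mice of different batches, all numbered 3 or 4, had correlations of -0.041, -0.058, -0.088, -0.172 and -0.26. Mice of 1 batch with different numbers reached 0.343. These values show no pairing by number apart from batch. With the number as a replicate block, NLRP3 knockout against WT gave 21 genes and 7 lists and sex 114 genes; no other count moved by over 1.5 times.

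The correlation of the transgene effects, 0.819, was 0.09303 in the largest cluster and 0.914 over called genes. The difference in marker share between double-mutant and NLRP3 knockout mice, 71.4 points, was 33.34 with 4 or more markers and 81.94 without thinning. With 4 or more markers, the difference for APP/PS1 against WT went from 63.01 to 37.96, for NLRP3 knockout against WT from 1.21 to 0.03321, and for double-mutant against APP/PS1 it turned from 9.607 to -4.591; without thinning they were 68.97, 0.7119 and 13.69. The 14 reversals were all in the largest cluster, which held 6 to 148 cells per mouse with the transgenes. There the log2 fold changes were 0.01947 for Grap, 0.07642 for Maf, -0.01023 for Ndufa2, -0.01008 for Cox6a1 and -0.04813 for mtCo1 in APP/PS1 against WT. In double-mutant against NLRP3 knockout they were -0.2656 for App, 0.09236 for Maf, -0.3161 for Bst2, -0.1864 for Cxcl16, -0.08926 for Got2, -0.08896 for Pdk1, -0.03158 for Cox5b, -0.08428 for Ndufa2 and -0.02115 for Npc2. None was called there.

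With each mouse left out, gene counts ran from 815 to 1633 for APP/PS1 against WT, 7 to 14 for NLRP3 knockout against WT, 12 to 21 for double-mutant against APP/PS1, 835 to 1749 for double-mutant against NLRP3 knockout, 0 to 0 for the interaction and 6 to 12 for sex. Lists ran from 12 to 13, 2 to 5, 3 to 5, 12 to 15 and, for the interaction, 5 to 9. The correlation ran from 0.7674 to 0.8351. Differences in marker share ran from 56.18 to 72.7 points for APP/PS1 against WT, 0.5813 to 1.698 for NLRP3 knockout against WT, -0.08964 to 16.44 for double-mutant against APP/PS1 and 68.69 to 74.76 for double-mutant against NLRP3 knockout. No share of clusters or difference in UMIs per cell was called, but so few mice leave their exact tests little room to pass after adjustment, so this says nothing about stability. Simulated 1.5-fold changes were recovered for 1.5% of genes in the interaction and 10.4% in double-mutant against APP/PS1. Most differences of that size, if present, would thus be missed there.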

Other observations

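In this part, the tests of positions and of flow cell for the genes called for NLRP3 loss and the test of flow cell and library batch for Slc1a3 were chosen after the result was seen, as were the genes of the next paragraph.

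Tmem163 and Dcstamp were close to silent in microglia without the transgenes, and Mmp12 in WT microglia. Tmem163 had 0 UMIs in WT and 195 in APP/PS1 mice, at least 44.0-fold higher, and 3 in NLRP3 knockout and 136 in double-mutant mice (ratio 73.7, 95% counting interval 24.7 to 362). Dcstamp, a transmembrane protein of cell fusion in osteoclasts, had 0 and 161 UMIs in WT and APP/PS1 mice, at least 36.3-fold higher, and 1 and 52 in NLRP3 knockout and double-mutant mice (ratio 84.5, 14.5 to 3400). Mmp12, macrophage elastase, had 2 UMIs in WT and 228 in APP/PS1 mice (ratio 77.2, 21.1 to 641). In NLRP3 knockout and double-mutant mice it had 27 and 56 UMIs, 2.54 ± 2.11 CPM (n = 5) and 9.21 ± 6.22 CPM (n = 3), and was not called (edgeR adjusted p = 0.0534). Prnp, whose untranslated sequences were used in a widely used APP/PS1 line, averaged 22.6 ± 13.3 CPM in APP/PS1 and 30.3 ± 9.55 CPM in double-mutant mice, against 1.60 ± 0.740 CPM in WT and 0.534 ± 0.538 CPM in NLRP3 knockout mice; which line was used is not given in the labels.

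The genes called for NLRP3 loss lay near each other on the chromosomes. Of 17 tested for this, which leave out Nlrp3, 6 had another within 2 Mb, where random draws of tested genes gave a mean of 0.792 (permutation p = 0.004 from 10000 draws). They were Tmem181c-ps, Ccr6, Mpc1 and Prr18 on chromosome 17 between 6610103 and 8344113, and Sgsh and Slc26a11 on chromosome 11 between 119343489 and 119381076. Within 20 Mb of Nlrp3 lay 0 called genes, so a segment of that reach does not account for this grouping. Random draws gave a mean of 0.541 there, so 0 is usual by chance. Whether a segment around Nlrp3 was carried with the knockout allele is therefore not decided. Flow cell is argued against for NLRP3 knockout against WT. With it as a term 98.5% of the median absolute log2 fold change was kept there, although only 4 of 7 genes were still called. In double-mutant against APP/PS1, 107% was kept and 4 of 16 genes were still called. Those groups share no flow cell, so the term rests on the other mice and cannot decide there. Segments of another strain elsewhere in the genome may account for the grouping, as a hypothesis found and tested on the same data; Sgsh and Slc26a11 adjoin in the annotation, and sharing of reads between them was not tested. An effect of NLRP3 itself on these genes was not tested.

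Slc1a3, a glutamate transporter, stood at separate levels among the NLRP3-null mice: 818, 1128, 227, 194 and 1052 CPM in NLRP3 knockout replicates 1 to 5 and 802, 95.4 and 817 CPM in double-mutant replicates 1 to 3, against 173 to 226 CPM in WT and 114 to 178 CPM in APP/PS1 mice. At the higher level 92.2 to 95.5% of microglia held a Slc1a3 UMI, against 34.5 to 59.2% in the other mice. RNA of astrocytes is argued against, since Slc1a2, Aldoc, Gja1 and Aqp4 together reached at most 2.74% of the Slc1a3 CPM in mice above 500 CPM. Flow cell and library batch are argued against as well, since 2 flow cells and 2 library batches held NLRP3-null mice of both levels. A variant that segregates among these mice may account for it and was not tested.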
